A study of Homo sapiens with 22 samples.

How the data were processed

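CTCF, the zinc-finger protein that marks the anchors of chromatin loops, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in CD4+ T cells selected from human blood. Per the labels' protocols, the cells were fixed with formaldehyde, the chromatin was precipitated with a commercial kit and libraries were sequenced on an Illumina HiSeq platform. Of the 22 libraries, 5 CTCF and 5 input libraries came from children with active juvenile idiopathic arthritis (JIA) on treatment, and 6 CTCF and 6 input libraries came from healthy controls. The library titles carry 5 sample codes per group, and each code was taken as 1 sample. Nothing else in the labels describes the source of a sample, so p-values measure the spread between these samples. The healthy sample numbered 2 had 2 CTCF libraries, and the healthy sample numbered 5 had 1 CTCF library with 2 peak lists, which gives 12 peak lists for 10 samples. The peak lists of the CTCF libraries were used, and the input libraries were not analysed here.

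Per the submitters' processing notes, Bowtie2, SAMtools and MACS2 were used with the hg19 genome build; versions and settings are not given in the sources used here. Each deposited file is a narrowPeak list with a start, an end and a summit per peak, and the peak names show 1 caller run per list with no pooling. The deposited fold enrichment of a peak is the ratio of fragments at the summit to the local background, as the authors' peak caller wrote it. The deposited −log10 p-value and −log10 q-value belong to the summit. The deposited score of each peak is 10 times the −log10 q-value, cut to a whole number for nearly all peaks. The smallest −log10 q-value in each list lay just above 1.3, the value of a q-value of 0.05, so the lists hold peaks down to that threshold. These values are the authors' own and were used to describe, rank and filter peaks within a list, never to compare a peak's fold between lists.

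The reference at hand was hg38, and no hg19 genome or gene annotation was used here. Coordinates were not converted, so peaks were not assigned to genes, exons or untranslated regions, the planned fixed gene lists were not tested, the regions planned to be named at those genes were not named, and the CTCF motif was not searched. Regions are therefore identified by their hg19 position, counted from 1. Peaks on the sex chromosomes were left out of every result, and peaks on unplaced contigs out of every comparison except 1, of the contig gl000220, in the closing section.

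The lists give no sequencing depth, but the number of fragments that the caller kept could be estimated. It is called depth here. MACS2 computes the fold enrichment as the summit pileup plus 1 over the local background plus 1, and the p-value from a Poisson tail, so both numbers together fix the pileup and the background. A whole-number pileup matched the deposited −log10 p-value within 0.001 for 100% of the peaks of each list, and on simulated data 99.995% of 20000 pileups were recovered. The lowest background in a list is the genome-wide one, reached by 12.8% to 20.3% of its peaks. The smallest peak width, 124 to 199 bp, was taken as the fragment length that the caller used. The highest pileup in each of the 12 lists stayed at or below 2 times that width, the ceiling that results if 1 fragment per position and strand is kept. Background divided by width is proportional to depth, and with an effective genome size of 2.7 Gb, assumed here, it gives depth in M fragments (M stands for 1000000). Depth ran from 3.88 to 19.6 M fragments. The estimates depend on that size and width, and the pileups do not. If duplicate fragments were dropped, a low estimate can come from little sequencing or from a library with many duplicates. The lists cannot tell these apart.

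Peak number and covered bases were compared between 5 JIA and 5 healthy samples by two-sided exact permutation tests over the 252 assignments of samples to groups, with the mean of the 2 lists for the healthy samples numbered 2 and 5. The smallest p this design allows is 0.00794. Overlap between lists was measured as the Jaccard index in base pairs, and the excess of within-group over between-group overlap was tested one-sided over the 126 splits of the samples. For regions, the list numbered 1 of each sample was used, overlapping peaks (1 bp or more) were merged, and regions called in at least 2 of the 10 lists were tested by Fisher's exact test on the number of samples with a peak, with Benjamini-Hochberg adjustment. Regions called in 5 of 5 samples of one group and 0 of 5 of the other were named by a fixed rule: up to 12 per direction, ranked by the mean percentile of the −log10 q-value within the lists that called them. The groups, tests, named-region rule and most alternatives were fixed before the data were examined. The shares of peaks by chromosome, the thinned lists and the tests of summit pileups and of 1 Mb windows were added afterwards. For thinning, each summit pileup was drawn from a binomial distribution down to the depth of the shallowest library, the background was scaled alike, and peaks with a −log10 p of at least 5 were kept; means of 20 draws are given, except for overlap and for named regions, where the first draw was used. Thinning does not search for summits again and leaves peak widths as deposited. A 95% interval for the difference in thinned peak number was taken as the shifts that the exact permutation test did not reject. In a further test added afterwards, each of the 5 healthy lists was thinned to the depth of a different JIA library, paired at random in 20 draws, and regions called in every healthy list and in none of the thinned ones were counted.

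Alternatives were a −log10 q of at least 5, lists of equal length (the 32787 peaks of highest −log10 q-value), other uses of the paired lists, other definitions of a shared region, and leaving out each sample in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and the interval code was checked against bedtools 2.31.1 on simulated lists, where 100% of 200 planted separating regions were recovered. limma 3.58.1 in R 4.3.3 was used for the pileup and window tests in the closing section, on log2(pileup + 0.5) after quantile normalization and on log2(peaks + 1) after median scaling.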

Results

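CTCF binding in CD4+ T cells was available as 12 peak lists from 10 samples, 5 from children with active JIA on treatment and 5 from healthy controls. The lists held 32787 to 65945 autosomal peaks. Estimated depth was 11.4, 4.64, 10.6, 3.88 and 7.06 M fragments (M stands for 1000000) in JIA samples 1 to 5. It was 11.1, 19.6, 19.6 and 18.2 M in healthy samples 1, 3, 4 and 5, and 15.4 and 13.5 M in the 2 libraries of healthy sample 2. The mean was 7.51 ± 3.39 M fragments in JIA and 16.6 ± 3.72 M in healthy samples (SD, n = 5 each; two-sided exact permutation test, p = 0.0159). The ranges of the groups overlapped only between 11.1 and 11.4 M fragments, so depth was confounded with group.

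Most of the strong CTCF sites were found in all samples. Merging the 10 lists gave 84561 autosomal regions, of which 65196 were called in at least 2 samples and 27958 in every JIA and every healthy sample. When peaks had to cover at least 50% of the merged region to count, 8881 regions were called in every sample. In each list, 99.9% to 100% of the peaks in the top 10% by −log10 q-value lay in these shared regions, against 6.39% to 51.7% of the peaks in the bottom 10%. The summit position in a shared region varied little between samples, with a median absolute deviation of 7.5 bp for the median region, and it was at or below 50 bp in 98.6% of the regions. In the healthy lists and in JIA sample 1, 201 to 2738 peaks per list reached 80% of the list's ceiling or more, against 1 to 10 in the other JIA lists, so median pileups do not rank the strongest sites. Among the sites with high pileups were chromosome 1, 121483943 to 121485533 (hg19, as all positions here), with a median of 261 fragments over the 10 lists, chromosome 10, 6130331 to 6131405, with 249.5, and chromosome 17, 41560778 to 41561521, with 248.5. By −log10 q-value they were at the 49.1st, 99.7th and 99.3rd percentile of the lists on average. The first was therefore not among the strongest sites by that value, which also depends on the local background. No autosomal positions were filtered out here as prone to artefacts. These 3 regions were chosen after their values were seen. The share of a list's peaks in shared regions was 67.7% ± 15.2 in JIA and 52.6% ± 4.15 in healthy samples (SD, n = 5 each; exact permutation p = 0.0635, two-sided). The shared regions are the same for every list, so this share mostly reflects list length. It was 88.7% in JIA sample 4 with 32787 peaks and 45.7% in JIA sample 1 with 65945.

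The study compared CTCF sites of children with JIA with those of healthy controls, and the first question was whether the number of sites differed. JIA samples had 46283 ± 12112 autosomal peaks and healthy samples 57125 ± 3782 (SD, n = 5 each), a difference of −10841 peaks. This was within the spread between samples (two-sided exact permutation test, p = 0.0952). The JIA sample numbered 1 had 65945 peaks, more than any healthy sample, while the JIA sample numbered 4 had 32787. Without JIA sample 1 the difference was −15757 peaks (exact permutation p = 0.00794). That sample was the deepest in JIA. Without it the depths no longer overlapped, at 3.88 to 10.6 M fragments in JIA and 11.1 to 19.6 M in healthy samples. The larger difference therefore cannot be told apart from depth. JIA peaks covered 18.5 ± 5.21 Mb and healthy peaks 24.6 ± 1.15 Mb of the autosomes (SD, n = 5 each; exact permutation p = 0.0476, two-sided). That call was lost when any sample other than JIA sample 1 was left out, with exact permutation p between 0.0635 and 0.0952. It was also lost after thinning to equal depth (−3.38 Mb, exact permutation p = 0.0873) and kept with lists of equal length (−3.33 Mb, exact permutation p = 0.0317). Median peak width was 358 ± 45.8 bp in JIA and 359 ± 39.5 bp in healthy samples, over full lists that differed in length. Lists of equal length hold the same number of peaks and covered 15.5 Mb in JIA and 18.9 Mb in healthy samples. The difference kept there is therefore one of peak width, which was not corrected for depth.

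**Figure D1:**
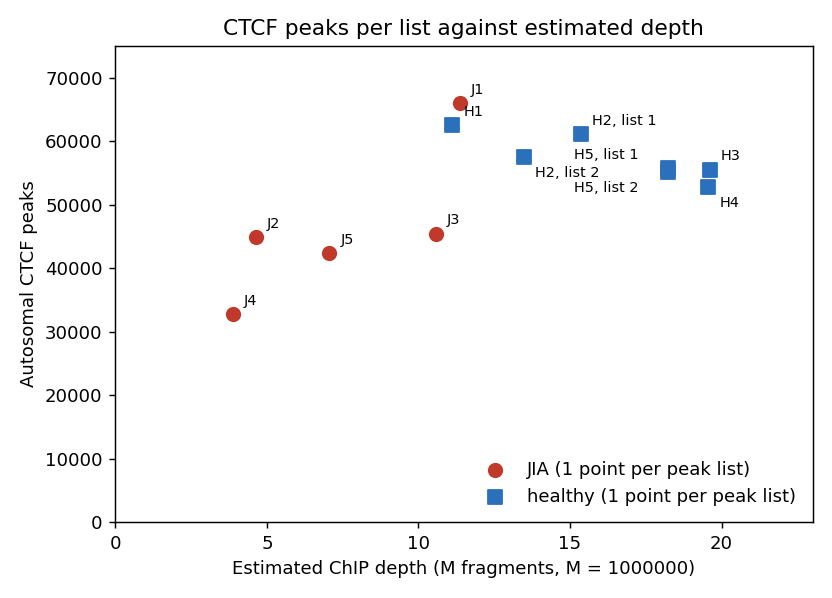
Autosomal CTCF peaks of each deposited list (vertical axis) against the estimated depth of its ChIP library (M fragments, horizontal axis); each point is 1 list, J marks JIA and H healthy samples, and the numbers are sample numbers. The JIA lists lie between 3.88 and 11.4 M fragments and the healthy ones between 11.1 and 19.6 M, and JIA sample 1 has the most peaks.

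Peak number and depth were then compared at equal depth, by thinning. At a −log10 p of at least 5, JIA samples had 45261 ± 11631 peaks and healthy samples 55695 ± 3727 before thinning (SD, n = 5 each), 18.7% lower in JIA. After thinning to the depth of the shallowest library they had 38610 ± 6405 and 38358 ± 4993 peaks, a difference of 252.2 peaks (two-sided exact permutation test, p = 0.976). The 95% interval from that test ran from −22.0% to 24.3% of the healthy mean. Depth was not the only thing that varied: JIA samples 1 and 3, at 11.4 and 10.6 M fragments, still had 47758 and 34133 peaks after thinning.

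**Figure D2:**
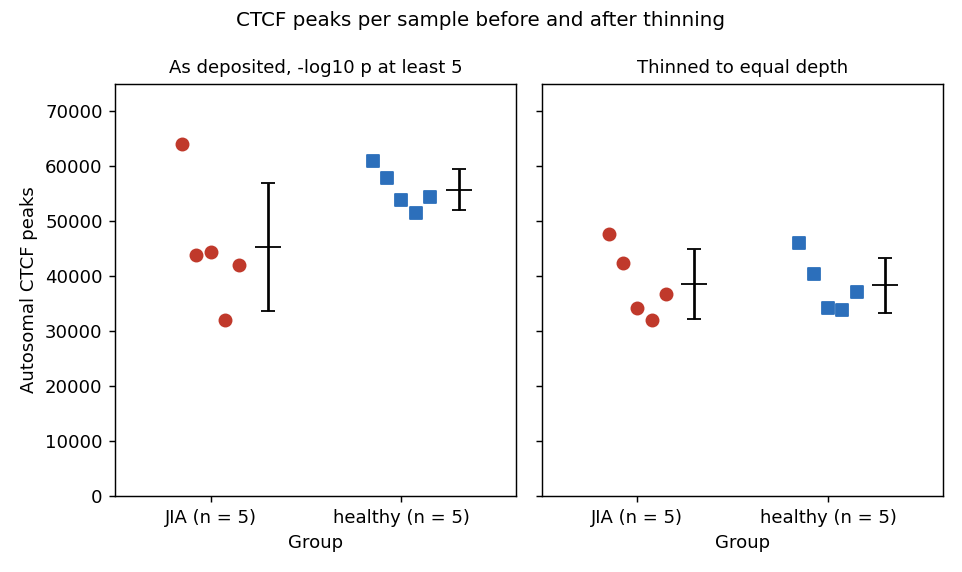
Autosomal CTCF peaks per sample with a −log10 p of at least 5, as deposited (left) and after thinning to the depth of the shallowest library (right, mean of 20 draws); points are samples, and the black marks are the group mean ± SD (n = 5). The group means differ by 18.7% on the left and by 0.66% on the right.

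The second question was whether samples of one group shared more of their CTCF sites with each other than with the other group. The mean Jaccard index was 0.642 for the 10 pairs of healthy samples, 0.568 for the 10 pairs of JIA samples and 0.572 for the 25 pairs across groups. The excess of within-group over between-group overlap was 0.033 (exact permutation over 126 splits, one-sided p = 0.0476). With all 10 samples it came from the healthy pairs, since the JIA pairs overlapped no more than the pairs across groups. JIA sample 1 overlapped the healthy lists more (mean Jaccard index 0.639) than the other JIA lists (0.523). The index cannot exceed the ratio of the smaller to the larger number of covered bases. JIA sample 1 covered 27.2 Mb, the other JIA lists 13.9 to 18.1 Mb and the healthy lists used here 23.5 to 26.9 Mb. Its lower index with JIA lists therefore follows at least in part from coverage, which was not separated from likeness of sites. The excess stayed past 0.05 with lists of equal length (0.022, exact one-sided p = 0.0476). It was no longer past 0.05 after thinning (0.017, exact one-sided p = 0.0635), and it was also lost without any 1 of the healthy samples or without JIA sample 2 or 4, with values between 0.020 and 0.031. Without JIA sample 1 it was 0.071 (exact one-sided p = 0.00794), but depth then separated the groups completely. As a technical scale, the 2 CTCF libraries of healthy sample 2 had a Jaccard index of 0.731, above every pair of different samples (0.463 to 0.688). For healthy sample 5 the labels name 1 CTCF library and 2 input libraries. Its 2 peak lists reached 0.882, which does not measure repeated ChIP because both lists belong to the same CTCF library. They shared 34656 summits, 62.1% of those in the first list. At 100% of the shared summits the solved pileup was identical, and the solved local background differed at 92.6% of them, while the genome-wide background was the same.

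The third question was which CTCF regions were gained or lost with disease. None of the 65196 regions passed Fisher's exact test after Benjamini-Hochberg adjustment (smallest adjusted p = 1), and with 5 samples per group the smallest unadjusted p is 0.00794. At an unadjusted p below 0.05 there were 1186 regions, 1181 called more often in healthy and 5 more often in JIA samples. The same counts were 106 and 38 with lists of equal length, 87.7 and 75 after thinning to equal depth, and 119.85 and 48.6 after thinning to an equal background, the thinned ones as means of 20 draws. Without JIA sample 1 there were 4041 regions called more often in healthy samples, and without any other 1 sample there were 1296 to 2283. Leaving out 1 sample makes an unadjusted p below 0.05 easier to reach, so these counts can rise whichever sample is left out. Without JIA sample 1 depth also separated the groups completely, for these counts and for the fully separating regions below. Regions called more often in JIA samples numbered 9 to 29 with 1 JIA sample left out and 6 to 18 with 1 healthy sample left out. With 100 bp windows around summits the counts were 1280 and 39, and where peaks had to cover at least 50% of a region they were 1832 and 8. Fully separating regions were also uneven: 85 were called in 5 of 5 healthy and 0 of 5 JIA samples, and 1 in 5 of 5 JIA and 0 of 5 healthy samples. With lists of equal length there were 5 healthy-only and 2 JIA-only regions, and after thinning to equal depth 5.45 and 10.45, as means of 20 draws. Both steps remove weak peaks of the longer and deeper healthy lists whatever the reason for their absence in JIA. Single samples also moved the number. Without JIA sample 1, 679 regions were healthy-only, and without JIA sample 3 or 5 or healthy sample 1, 2, 3 or 4 there were 135 to 176, where fewer samples have to separate. JIA-only regions numbered 4 without healthy sample 3 and 2 without JIA sample 4.

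The 85 healthy-only regions were weak peaks spread over 22 chromosomes, at most 7 on one. Their mean percentile of −log10 q-value within the lists that called them ranged from 7.43 to 40.6 with a median of 20.1, their median summit pileup was 13 fragments, and none lay above the median of its lists. The strongest was chromosome 8, 2585374 to 2585787, at the 40.6th percentile with 20 fragments. It was followed by chromosome 2, 30461176 to 30461596 (34.4th percentile), chromosome 2, 214013366 to 214013677 (33.4th), and chromosome 9, 127998766 to 127999026 (32.5th). The other 8 named regions lay between the 27.6th and 31.1st percentile. They were chromosome 14, 77466766 to 77467154, chromosome 1, 38470100 to 38470383, chromosome 15, 75087166 to 75087660, and chromosome 3, 49466180 to 49466429. The last were chromosome 10, 89195076 to 89195233, chromosome 1, 1509238 to 1509499, chromosome 9, 130678794 to 130679621, and chromosome 21, 44780948 to 44781320. Of these 12 named regions, 0 stayed fully separating with lists of equal length and 0 after thinning to equal depth. The single JIA-only region was chromosome 17, 57401516 to 57401857, with its summit at 57401721. It was at the 45.2nd percentile with a median of 20 fragments, and it stayed in 5 of 5 JIA and 0 of 5 healthy samples under the 10 other ways of filtering, thinning or merging the lists. Filtering and thinning only remove peaks, so they could not add a healthy peak there. Other uses of the paired lists left the JIA lists unchanged. The region was also chosen for its lack of healthy peaks, so its persistence is weak evidence of stability. Its Fisher's exact p of 0.00794 gives an adjusted p of 1.

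**Figure D3:**
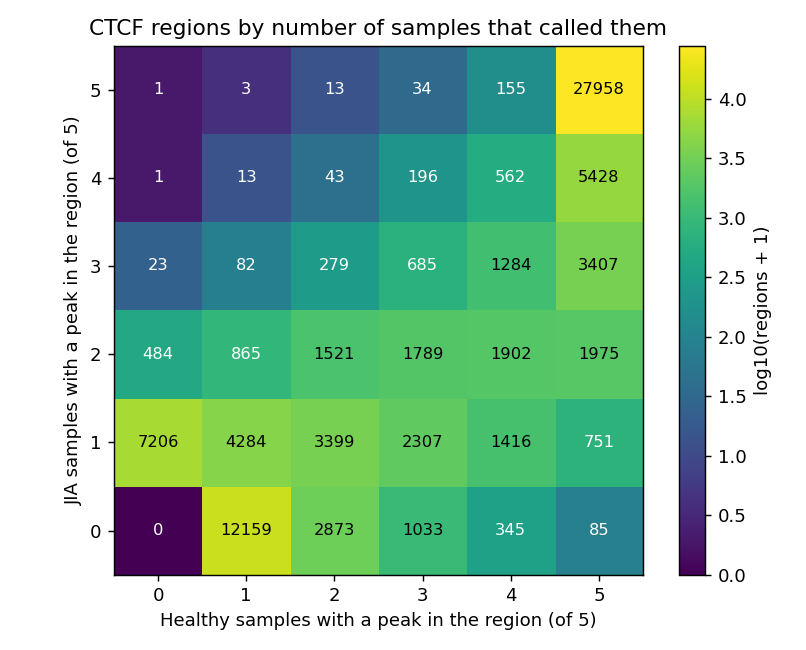
Number of autosomal CTCF regions by how many JIA samples (vertical axis, of 5) and how many healthy samples (horizontal axis, of 5) had a peak there; colour is log10 of the number plus 1. The corner of all 10 samples holds 27958 regions, the healthy-only corner 85 and the JIA-only corner 1.

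The share of peaks on each autosome was compared between the groups. Chromosome 1 held 10.3% ± 0.10 of the JIA and 10.3% ± 0.12 of the healthy peaks, chromosome 19, which is small and gene-dense, 4.93% ± 0.38 and 5.01% ± 0.35, and chromosome 18, which is gene-poor, 1.82% ± 0.11 and 1.83% ± 0.06 (SD, n = 5 each). In exact permutation tests, 0 of the 22 chromosomes had an unadjusted p below 0.05, and the smallest was 0.103, for chromosome 7 (5.29% ± 0.037 in JIA and 5.25% ± 0.030 in healthy samples; adjusted p = 1). At a −log10 q of at least 5, chromosome 12 had an exact permutation p of 0.0159 (5.32% in JIA and 5.15% in healthy samples; adjusted p = 0.349).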

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

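The test of enrichment and both ways of thinning were added after related values had been seen. What thinning had to show was written down before its result; lists of equal length were chosen before the values were seen, but what they had to show was written afterwards. Outlying samples were looked for in 62 groups of values, and 1 was found where chance gives about 3.1.

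Healthy sample 1 stood apart in enrichment, taken here as the ratio of pileup to background. At the shared regions its median summit pileup over the genome-wide background was 215, against 114 to 128 in the other healthy samples. The pileup itself was similar, at 110 fragments against 109 to 124. The background was lower, at 0.511 against 0.854 to 0.971 in the lists numbered 1, so the ratio stood apart through the background. JIA samples 1 and 2 were also high, at 214 and 182, and the other JIA samples lay between 84.0 and 116. The labels name no batch, and no biological explanation was tested for this.

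A signal outside the comparisons was found on the unplaced contig gl000220. It carried a median of 21.25 CTCF peaks per sample, from 9 to 37, with 18.8 ± 11.2 in JIA and 22.3 ± 7.51 in healthy samples (SD, n = 5 each; two-sided exact permutation test, p = 0.571). No explanation was tested.

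The lower peak number in JIA is consistent with lower depth: the difference went from −18.7% of the healthy mean to 0.66% after thinning to equal depth, and to −2.27% after thinning to an equal background. The 95% interval after thinning to equal depth ran from −22.0% to 24.3%, which includes the difference before thinning. Thinning keeps the deposited summits and does not search for new ones, which could take more peaks from the deeper, healthy libraries than a lower fragment number would. Weaker enrichment of the JIA libraries remains open, because the median enrichment differed between the groups by 0.18 (exact permutation p = 0.992) with SDs of 53.7 in JIA and 41.4 in healthy samples. An effect of the disease or its treatment on the number of sites also stays open, since depth was confounded with group.

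Depth and list length were also weighed for the 85 healthy-only regions, and neither was decided. At a −log10 p of at least 5 there were 83. Thinning to equal depth left 5.45 on average (3 to 8 over the 20 draws) and lists of equal length left 5, but peaks with a median of 13 fragments drop out under both steps whatever the cause. With each healthy library thinned to the depth of a JIA library instead, 11.75 regions on average were called in every healthy list and in none of the thinned ones, from 0 to 39 over 20 draws. That is below the 83 observed. The thinned peaks come from regions chosen for being called in every healthy list, which could make this number too low, so the role of depth stays open. Among 100 splits of the 10 samples, the real one included, 9 gave at least the 86 fully separating regions of the real split, so chance cannot be excluded. The highest of the other splits gave 343. It set JIA sample 1 with healthy samples 1, 2, 3 and 5 apart from the rest, which are the samples with the 5 longest lists. Loss of these sites in disease stays open: no region passed the adjusted test, and the design could hardly have let one pass.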

How the results depend on the processing

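Alternatives with thinned lists or a −log10 p minimum, and those of the chromosome and pileup tests, were chosen after the data were seen. The difference in peak number stayed negative in all alternatives except thinning to equal depth, where it was 252.2 peaks; with 1 sample left out it ran from −15757 to −7467. The difference in covered bases kept its sign and fell from −6.15 Mb to −3.38 Mb after thinning to equal depth and −3.76 Mb after thinning to an equal background, no longer past 0.05. With lists of equal length it was −3.33 Mb and still past it. Peak widths were not thinned, so these values do not remove the effect of depth on width. With 1 sample left out it ran from −8.33 to −5.01 Mb. The excess of within-group overlap was 0.017 and 0.019 in the same thinned lists and 0.012 as a share of peaks overlapping by 1 bp, none past 0.05, and 0.020 to 0.071 with 1 sample left out. It was 0.022 with equal list lengths, 0.038 at a −log10 q of at least 5 and 0.028 with 50% reciprocal overlap, all past 0.05. Lower depth in JIA kept its call without any 1 sample (−10.5 to −8.17 M fragments). Healthy-only and JIA-only regions numbered 5 and 2 with equal list lengths, 5.45 and 10.45 after thinning to equal depth, 7.7 and 8.4 after thinning to an equal background, and 1181 and 5 when a difference of at least 4 samples was enough. With that difference there were 106 and 38 with equal list lengths, 87.7 and 75 after thinning to equal depth, and 119.85 and 48.6 after thinning to an equal background. JIA-only regions numbered 2 at a −log10 q of at least 5 and where peaks had to cover at least 50% of a region, and 3 with 100 bp windows around summits. With 1 sample left out, healthy-only regions ranged from 94 to 679 and JIA-only regions from 1 to 4; fewer samples make full separation easier. The adjusted Fisher test called 0 regions in every alternative, which says nothing about stability, since the smallest p of the design, 0.00794, could pass the adjustment only if a large part of all regions separated the groups. After adjustment 0 of 22 chromosome shares passed in every alternative; at a −log10 q of at least 5, chromosome 12 had an unadjusted p of 0.0159 (exact permutation). Of 130 values of the 13 named regions under alternatives, 82 kept full separation, 48 did not and 0 reversed. Filtering and thinning only remove peaks, so they could not reverse a region, and the 0 reversed says nothing about stability. Other uses of the paired lists left the JIA lists unchanged. Of the 12 named healthy-only regions, 0 stayed fully separating with equal list lengths and 0 after thinning to equal depth. After thinning to an equal background 1 did. The pileup test called 0 regions in all alternatives except without JIA sample 4, with 1 region; the cause of these changes was not tested. Gene annotation, gene lists and motifs were not run for want of an hg19 reference here. No paired analysis was possible because no label ties a JIA to a healthy sample. Lists of equal length give no value for peak number. Weak peaks such as the healthy-only ones, with a median of 13 fragments, drop out on thinning whatever the cause of their absence in JIA.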

Other observations

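All tests in this part were chosen after the lists had been read. CTCF sites shared by all samples were unevenly spread. Neighbouring shared regions lay a median of 36.8 kb apart, with 10% closer than 4.08 kb and 10% farther than 198 kb. A 1 Mb window with any shared region held a median of 10. The densest was 106 to 107 Mb on chromosome 14 with 58 shared regions, followed by 42 to 43 Mb and 48 to 49 Mb on chromosome 19 with 54 and 51, 156 to 157 Mb on chromosome 1 with 49, and 65 to 66 Mb on chromosome 11 and 7 to 8 Mb on chromosome 17 with 48 each (hg19).

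A hypothesis was that CTCF occupancy differs in strength at sites called in all samples. Summit pileups at the 27958 shared regions were compared with limma. After Benjamini-Hochberg adjustment 0 regions passed 0.05 (smallest adjusted p = 0.998), and 1092 had an unadjusted p below 0.05. Median scaling in place of quantile normalization also gave 0 regions (3366 unadjusted), as did the log2 depth as a covariate (507 unadjusted). The 1092 and the 507 are below a share of 0.05 of the regions, and the 3366 are above it. Both kinds of scaling take out a difference common to all regions, so a difference in overall strength was not tested. On simulated pileups for the same comparison and number of regions, 60 of 100 regions changed 2-fold and 4 of 100 changed 1.5-fold were called, so changes of 1.5-fold would mostly be missed. The simulation used 1 fixed spread, not one estimated from the real lists, and no pileup ceiling, so the real shares may differ. Of 100 splits of the samples, 100 gave at least as many regions, which the real count of 0 makes certain. Any call was made in 9 splits, the highest count was 576 and the next 12. The highest split set JIA samples 1, 2 and 3 with healthy samples 3 and 4 apart from the rest, and its cause was not tested. Pileups near the ceiling can hide differences at the strongest sites. The share of peaks at 80% of the ceiling or above was 0.329% to 4.93% in the healthy samples, 1.71% in JIA sample 1 and 0.0022% to 0.022% in the other JIA samples.

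A further hypothesis was that JIA changes the number of CTCF sites over whole domains. With lists of equal length, 0 of 1966 windows of 1 Mb passed 0.05 after adjustment in limma (smallest adjusted p = 0.812), and 108 windows had an unadjusted p below 0.05, or 5.49%. With the lists as deposited 0 of 2168 windows passed in limma (smallest adjusted p = 0.0629), and 184, or 8.49%, had an unadjusted p below 0.05. With thinned lists 0 of 2054 passed (smallest adjusted p = 0.997), and 70 did so unadjusted. With lists of equal length, the window with the smallest p was 15 to 16 Mb on chromosome 19, with 17.2 ± 1.10 peaks in JIA and 21.4 ± 1.95 in healthy lists (SD, n = 5 each; limma, adjusted p = 0.812).

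In the deposited lists, the window at 42 to 43 Mb on chromosome 10 held 52 peaks in JIA sample 3, 36 in JIA sample 2 and 11 to 21 in the other JIA samples, against 32 and 14 in healthy samples 3 and 4 and 5 in each of the other healthy samples. It was picked after its values were seen. No autosomal positions prone to artefacts were filtered out, so an artefact of the position cannot be excluded for this window. With lists of equal length it held 18.4 ± 14.6 peaks in JIA and 2.8 ± 1.10 in healthy samples (SD, n = 5 each, limma adjusted p = 0.812). The lists of healthy sample 5, which per the labels belong to 1 CTCF library, held 55815 and 55109 peaks, and 94.9% of the first list's peaks overlapped the second.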
